A study of Mus musculus with 10 samples.

How the data were processed

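Total RNA from mouse liver was labelled with biotin after whole-transcript amplification and hybridised to Affymetrix gene arrays, 1 array per mouse, per the labels' protocols. The deposited table holds log2 expression values for 35556 probe sets on 10 arrays, and the submitters' processing notes name RMA and Partek. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a set on the log2 scale, so small global shifts between groups would be removed. The versions, the RMA options and the processing date of the arrays are not given in the sources used here. No scanner files were used here, so signal over background was not measured per probe and low values carry no detection call.

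Arrays were assigned to groups by their titles, which name the virus each mouse received: 5 arrays from mice given Cre (HDAC3-depleted) and 5 from mice given GFP (control). The free-text descriptions name a different deacetylase for each replicate of a group and were not used for this. Every one of the 10 columns carried a sample title, and 0 columns were left unused. Probe sets were named through the platform annotation. In it 21789 probe sets had exactly 1 gene symbol, 1621 had several and 12146 had none listed. Among the probe sets with 1 symbol, 21698 matched a RefSeq gene table by Entrez gene number, and 0 symbols had to be updated. Probe sets with several symbols or none were kept out of the gene tests and counted separately. A gene with more than 1 probe set (999 genes) was represented by the one with the highest mean over all 10 arrays, which left 19938 genes. No gene was left out for being dim, and no further normalization was applied.

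HDAC3-depleted arrays were compared with control arrays by limma 3.58.1 in R 4.3.3, with lmFit and eBayes at their default settings, 2-sided, with the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes were called, and a fold of at least 1.5 was counted beside this. The level of Hdac3 was also compared by an exact 2-sided permutation test over all assignments of the arrays to the groups. The number of arrays, 5 per group, limits the precision of each value. The p-values measure the spread between these mice, each on its own array. Any batch of handling or hybridisation is not given in the sources used here, so its part in that spread is unknown.

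Gene lists were fixed before the data were examined, from textbook knowledge of liver, of HDAC3 and of cell types a liver piece can hold: NCoR complex and its recruiters, other histone deacetylases, circadian clock, fatty acid synthesis, triglyceride synthesis, lipid droplet and lipolysis, fatty acid uptake and binding, fatty acid oxidation and ketogenesis, cholesterol synthesis, bile acid synthesis and transport, lipoproteins, gluconeogenesis and glycogen, glycolysis and pentose phosphate, mitochondrial respiration, cytochrome P450 drug metabolism, male-biased and female-biased liver genes, hepatocyte regulators and plasma proteins, fetal liver genes, Kupffer cell and macrophage, lymphocyte, neutrophil, stellate cell and matrix, sinusoidal endothelial cell, cholangiocyte, red blood cell, adipose or pancreas carry-over, cell cycle, p53 and DNA damage, unfolded protein and integrated stress response, acute phase, interferon response, and immediate early genes. Of 573 entries in the 33 lists, 510 were measured, 1 of them through an older symbol. The others were not analysed here. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 32 lists, with camera at an estimated correlation and fry beside it. Camera asks whether a list moved relative to all other genes. Fry asks whether its members moved one way on balance, without comparing them with other genes. The mean of each list per array was also compared by an exact permutation test over the arrays, a test added after the data were seen.

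The genes named were chosen by a rule set before the data were examined. It takes Hdac3, the 10 genes with the largest change in each direction among those called, up to 4 called members of each list with the largest change (or the 1 or 2 with the smallest adjusted p where no member was called), and any member of the circadian clock and NCoR lists. Predicted or clone-named transcripts were passed over in the top 10, 1 in each direction. The rule names 110 genes, and genes outside it are identified where they appear.

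The fit and the list tests were tested on simulated data first, in 20 runs of 19938 genes with 200 of them changed and the spread of the real arrays. The fit recovered 52.6% of genes changed 1.2-fold, 95.9% of those changed 1.5-fold and 99.6% of those changed 2-fold, and 5.16% of the calls were false. Each gene was drawn independently of the others, so these runs could not check the list tests for genes that vary together. Far fewer genes were changed than the 2338 called in the real data. Alternatives set in advance were quantile normalization, median centring, leaving out genes under the 30th percentile of mean level, the mean of a gene's probe sets, a fit on all probe sets, a trended and robust variance, array weights, the replicate number as a block, a stricter threshold, and leaving out each array in turn. Cyclic loess normalization was added after the data were seen. Groups were also compared with 100 of the 126 possible splits of the 10 arrays into 5 and 5, the real one included.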

Results

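Gene expression was measured in the livers of 10 male C57Bl/6 mice whose genotype label gives floxed Hdac3 alleles, which Cre recombinase can inactivate, although the growth protocol calls the mice wild type. Hdac3 encodes a histone deacetylase that acts in corepressor complexes with the NCoR proteins. At 11 weeks of age each mouse was injected through the tail vein with 1.5e11 particles of adeno-associated virus. The virus carried the Tbg promoter, which is active in hepatocytes, and expressed either Cre (5 mice, HDAC3-depleted) or green fluorescent protein (5 mice, control). The comparison asks which liver transcripts differ when hepatocytes lose HDAC3, and the groups also differ in the protein the virus expressed. Feeding state, hour of collection and the time from injection to collection are not given in the sources used here. Array medians lay between 6.85 and 6.88 on the log2 scale, and the median SD over genes was 0.088 in each group. The first principal component held 38.6% of the variance and separated the groups, with control 1 at -3.58, the other controls between -12.8 and -11.5, and the depleted arrays between 6.65 and 14.4.

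HDAC3-depleted livers had less Hdac3 transcript than control livers and more transcript of many genes of lipid storage, lipid synthesis and fatty acid oxidation. Cidec, a lipid droplet protein, rose 2.33-fold and G0s2, an inhibitor of triglyceride hydrolysis, rose 2.16-fold. The clock genes Arntl and Clock rose, while the clock output gene Dbp did not pass the test. Nox4, an NADPH oxidase, and Hsd3b5, a steroid dehydrogenase typical of male liver, fell 2.50-fold and 2.28-fold.

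Hdac3 fell from 10.89 ± 0.07 in control to 9.54 ± 0.13 in depleted livers (log2, SD, n = 5 each), a log2 difference of -1.36 (SE 0.06, 95% interval -1.49 to -1.22) with a limma adjusted p of 1.48e-07 and an exact permutation p of 0.00794, the smallest that reassigning the arrays can give. The control arrays read 10.94, 10.88, 10.78, 10.91 and 10.96 for replicates 1 to 5, and the depleted arrays 9.63, 9.59, 9.31, 9.54 and 9.62, so all 5 depleted arrays lay below all controls. The remaining signal was 39.1% of control (95% interval 35.5% to 42.9%), and Hdac3 had the smallest p of the 19938 genes. It is read by 1 probe set (10458461, chromosome 18), which may hold probes outside the deleted part. Liver RNA also comes from cells other than hepatocytes, in which the Tbg promoter may not act. The remaining signal is therefore not the share of intact transcript in hepatocytes, and these sources were not told apart.

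Among 19938 genes, 1228 were higher and 1110 lower in the depleted livers at an adjusted p under 0.05, 11.7% of all genes. Most of these differences were small, with a median size of 0.25 on the log2 scale (1.19-fold), and 66 genes were at least 1.5-fold higher and 43 at least 1.5-fold lower. The counts depended on single arrays. They were 817 higher and 729 lower without control 2, and 792 higher without control 3.

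Among genes past the threshold that have a gene name, the largest increases were in Atp6v0d2, a subunit of a vacuolar proton pump (2.82-fold, adjusted p = 0.000228), Slc16a5, of the monocarboxylate transporter family (log2 difference 1.46), Car14, a membrane carbonic anhydrase (1.43, SE 0.08, adjusted p = 6.97e-07), and the water channel Aqp8 (1.29). Orm3 (1.27), Cidec (1.22), Acnat2 (from 8.26 to 9.46), the organic anion exporter Abcc4 (1.12), G0s2 (1.11) and Serpina7, which encodes thyroxine-binding globulin (1.07), followed. The largest decreases past the threshold were in Cabyr (-1.48, SE 0.28, adjusted p = 0.00432), Hdac3, Nox4 (-1.32, SE 0.09, adjusted p = 2.27e-06), Hsd3b5 (-1.19), Pcp4l1 (-1.19), the desmosomal cadherin Dsg1c (-1.11), the glycolytic aldolase Aldoc (-1.10), the nicotinamide methyltransferase Nnmt (-1.08), Susd4 (-1.04) and Adgrf1 (from 8.88 to 7.88). Orm3, Acnat2, Hsd3b5 and Dsg1c have close paralogs whose RNA could share probes, so their assignment to 1 gene is uncertain.

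**Figure D1:**
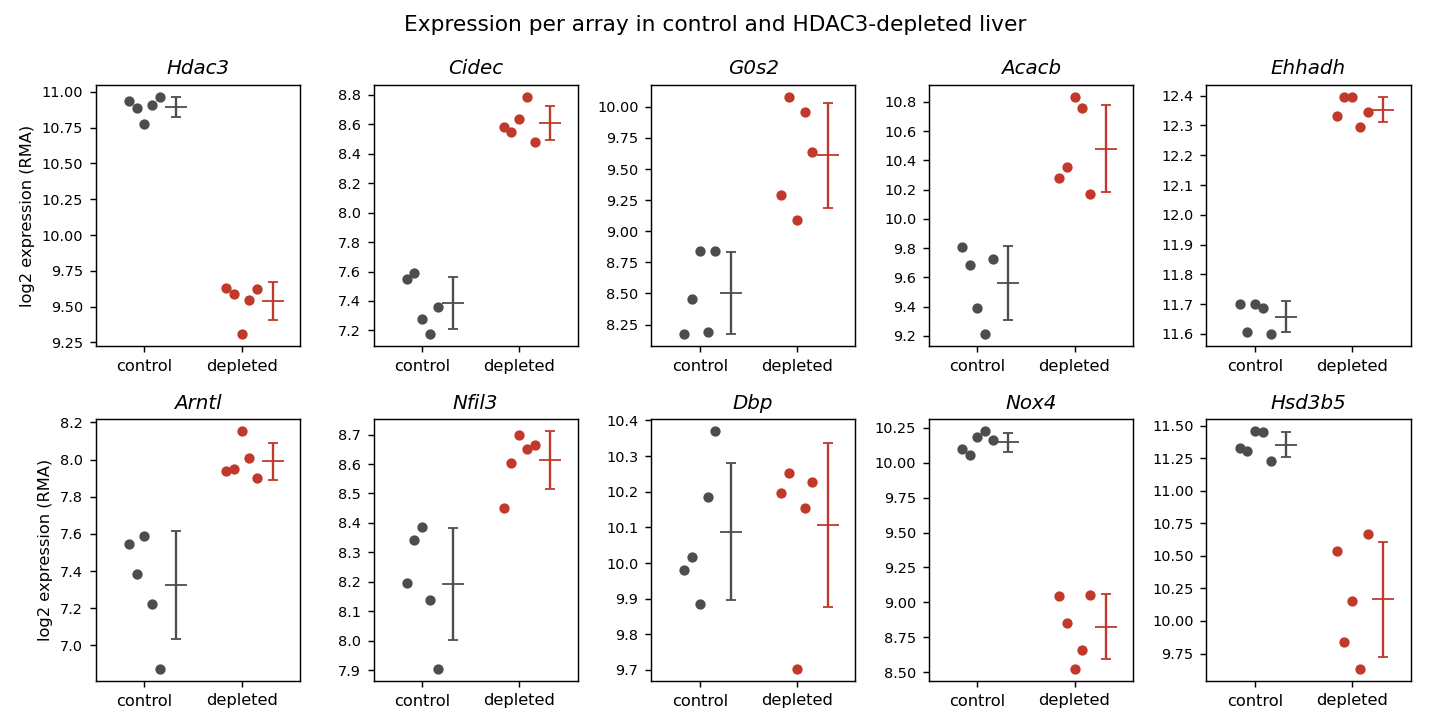
Log2 RMA expression of 10 genes on each array, with control arrays in grey and HDAC3-depleted arrays in red; points are mice, and the bar beside each group is its mean with its SD (n = 5). Hdac3 lies between 10.78 and 10.96 in control and between 9.31 and 9.63 in depleted livers, while the groups overlap for Dbp; each panel has its own axis, which does not start at 0.

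Of 18 measured lipid droplet and lipolysis genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone). The list was higher by camera at the preset correlation (adjusted p = 0.000213) but did not pass with an estimated correlation (adjusted p = 0.359). Cidec and G0s2 rose most, followed by hormone-sensitive lipase, Lipe (log2 difference 0.59), and Abhd5, an activator of triglyceride hydrolysis (0.50). Of 13 triglyceride synthesis genes, 5 rose and 0 fell (7 and 1 adjusted over the list alone), among them the acyltransferases Gpam (0.60), Gpat3 (0.36), Agpat2 (0.28) and Gpat4 (0.20). Calls of Gpat3 and Gpat4 were lost in 3 and 6 of the 10 fits that left out 1 array, up to adjusted p values of 0.0553 without HDAC3-depleted 4 and 0.108 without control 2. For triglyceride synthesis the camera adjusted p was 0.0153, against an adjusted p = 0.359 with an estimated correlation. The per-array means were 0.30 higher for the droplet list and 0.14 higher for triglyceride synthesis, each with an exact permutation p of 0.00794 (0.0327 adjusted over 33 lists).

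Fatty acid synthesis and fatty acid oxidation lists were higher by camera at the preset correlation (adjusted p = 0.00158 and 0.000192), and neither passed with an estimated correlation (adjusted p = 0.471 and 0.359). Of 18 synthesis genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), led by Acacb, the acetyl-CoA carboxylase of the mitochondrial surface (0.91), Thrsp (0.73), the elongase Elovl6 (0.57) and fatty acid synthase, Fasn (0.51). The Fasn call was lost in 8 of the 10 fits that left out 1 array, with its highest adjusted p, 0.0967, without HDAC3-depleted 4. Of 22 oxidation and ketogenesis genes, 13 rose and 0 fell (15 and 2 adjusted over the list alone). The peroxisomal enzyme Ehhadh (0.69, SE 0.04, adjusted p = 1.13e-06), the thiolase Acaa1b (0.58) and the fatty acid hydroxylase Cyp4a10 (0.39) were among them, and Pdk4, which inhibits pyruvate dehydrogenase, rose by 0.65. The Pdk4 call was lost in 2 of those fits, up to a limma adjusted p of 0.0627 without HDAC3-depleted 4. Cpt1a (-0.14) and Bdh1 (-0.15), named after their values were seen, were the 2 oxidation and ketogenesis genes lower when adjusted over the list alone. Per-array means were 0.27 higher for synthesis (exact permutation p = 0.0159, 0.0524 adjusted over 33 lists) and 0.19 higher for oxidation (exact permutation p = 0.00794, 0.0327 adjusted).

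Other lipid and energy lists did not pass camera. Of 11 uptake and binding genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.118): Fabp2 (0.45), the fatty acid translocase Cd36 (0.37) and Slc27a1 (0.32). Of 21 mitochondrial respiration genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.109), with citrate synthase, Cs, at 0.46, Cox5a at 0.22, Sdhb at 0.21 and Uqcrfs1 at 0.18. Calls of Sdhb and Uqcrfs1 were lost in 2 and 7 of the fits without 1 array, up to 0.0539 without control 2 and 0.0766 without control 4. The uptake and respiration lists each had an exact permutation p of 0.00794 for the per-array mean (0.0327 adjusted over 33 lists). Of 20 cholesterol synthesis genes, 0 rose and 1, Idi1, fell (-0.38), or 1 and 2 adjusted over the list alone (camera adjusted p = 0.0673). Idi1 has 2 probe sets, of which the brighter was used, and its difference lay between -0.464 and -0.338 over the alternatives. Which locus the brighter probe set reads was not checked. Of 14 lipoprotein genes, 0 rose and 1, Apom, fell (-0.23; 0 and 1 adjusted over the list alone; camera adjusted p = 0.643). Of 17 gluconeogenesis and glycogen genes, 3 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.128). The glycogen enzymes Gbe1 (0.33) and Pygl (0.30) and pyruvate carboxylase, Pcx (0.31), rose, while the coactivator Ppargc1a (-0.39) fell. Glycogen synthase, Gys2 (-0.27), and glucose-6-phosphatase, G6pc (-0.22), named after their values were seen, were the others that fell. Of 13 glycolysis and pentose phosphate genes, Taldo1 rose (0.22) and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.195).

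**Figure D2:**
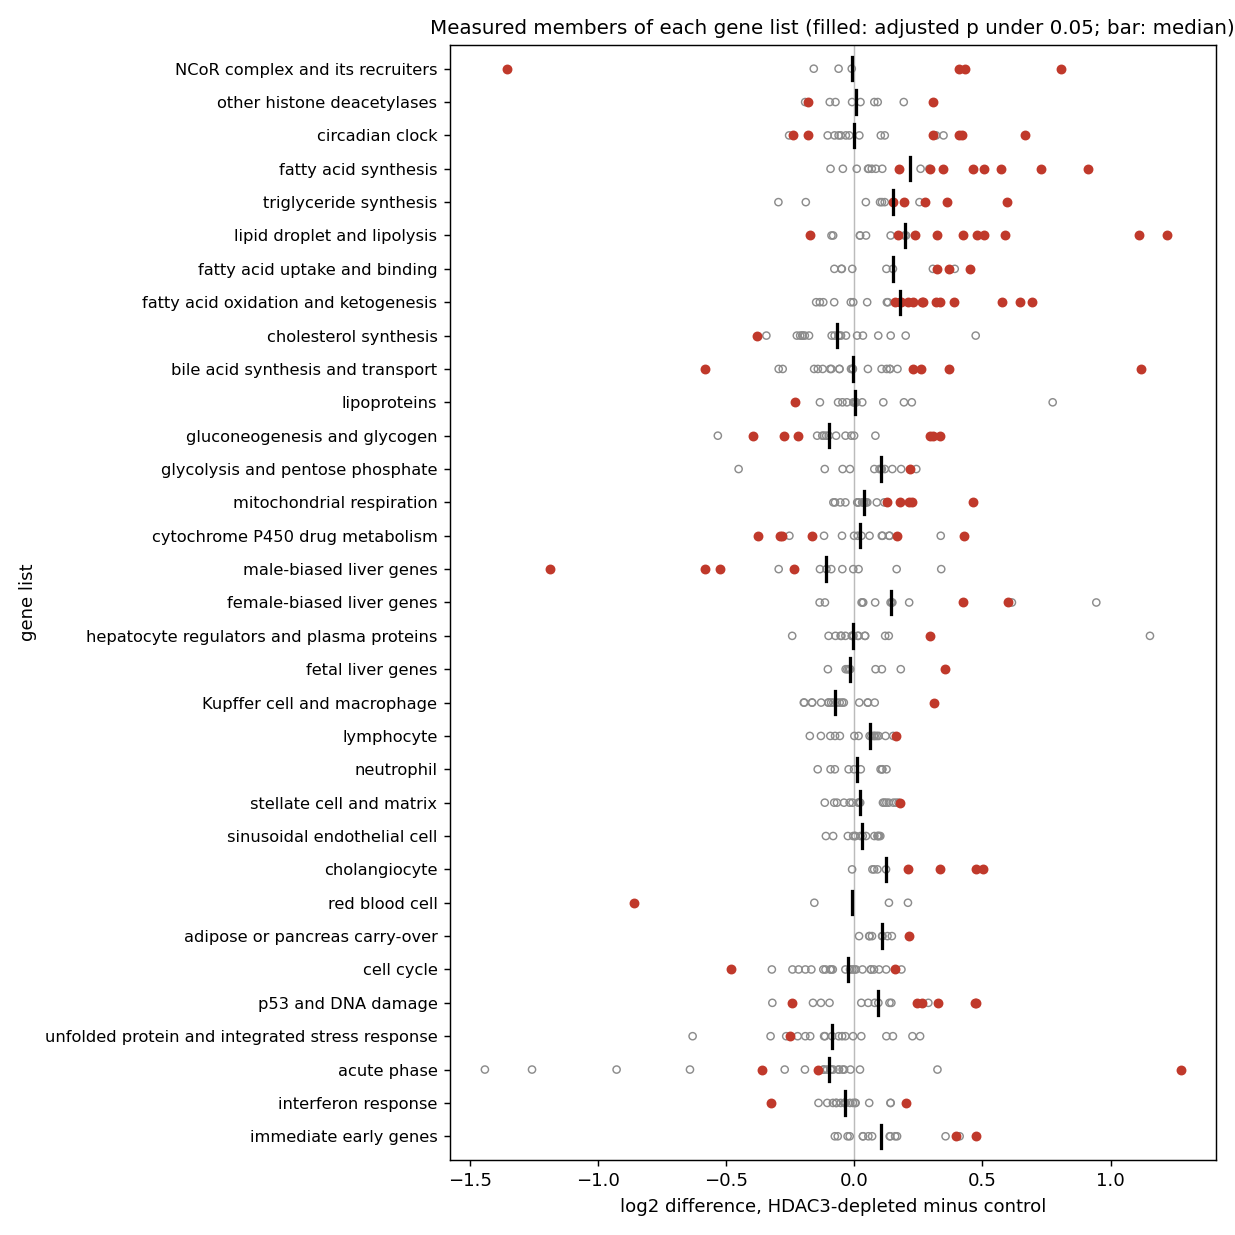
Log2 difference (HDAC3-depleted minus control) of each measured member of the 33 gene lists, 1 row per list; filled red points passed an adjusted p of 0.05, open grey points did not, and the black bar is the list's median. The fatty acid oxidation row has 13 filled points, all to the right of 0, and the male-biased row 4 filled points, all to the left.

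Clock genes moved in both directions. Of 18 measured, 4 rose and 2 fell (4 and 3 adjusted over the list alone). The activators Arntl (0.67, SE 0.11, adjusted p = 0.00195) and Clock (0.31) rose, as did the repressors Nfil3 (0.42) and Nr1d1, which encodes Rev-erb alpha (0.41). Cry1 (-0.24) and Per2 (-0.18) fell. Dbp (0.02), Tef (-0.08), Per3 (-0.03) and Usp2 (-0.05) did not pass the test, and Per1 (-0.26) had an adjusted p of 0.0602. The list did not pass camera (adjusted p = 0.792). Calls of Nr1d1, Cry1 and Per2 were lost in 3, 4 and 8 of the 10 fits that left out 1 array. Their highest adjusted p values were 0.0568 and 0.0674 without control 3 for Nr1d1 and Cry1, and 0.115 without control 4 for Per2.

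Partners of HDAC3 in its corepressor complex differed. Tbl1xr1 rose by 0.81 (SE 0.06, adjusted p = 3.3e-06) and Tbl1x by 0.43 (SE 0.05, adjusted p = 0.000145), while Gps2 differed by -0.01 and did not pass. Of the 7 measured genes of the NCoR list, 3 rose and 1, Hdac3, fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.649). Among 10 other histone deacetylases, Hdac5 rose (0.31) and Hdac4 fell (-0.18), or 1 and 2 adjusted over the list alone, and the camera adjusted p was 0.771. Both calls were lost when some single arrays were left out, up to an adjusted p of 0.0565 without HDAC3-depleted 4 for Hdac5 and of 0.0683 without control 3 for Hdac4. With the mean of its probe sets in place of the brightest, Hdac4 differed by -0.10 with an adjusted p of 0.159.

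The list of genes with a male bias in liver was lower by camera at the preset correlation (adjusted p = 0.00306), but did not pass with an estimated correlation (adjusted p = 0.471) or by fry (adjusted p = 0.0690). Of 13 measured, 0 rose and 4 fell (2 and 5 adjusted over the list alone): Hsd3b5 (-1.19), the organic anion transporter Slco1a1 (-0.58), the complement component C6 (-0.53) and Gstp1 (-0.24). The per-array mean was -0.21 (exact permutation p = 0.0317, 0.0806 adjusted over 33 lists). Of 14 female-biased genes, Cyp17a1 (0.60) and Sult3a1 (0.42) rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.128), with Sult3a1 at a level of 3.33 in control, near the low end of the arrays. The female-biased list passed fry (adjusted p = 0.00967), and its per-array mean was 0.225 higher (exact permutation p = 0.0159, 0.0524 adjusted over 33 lists). Of 24 bile acid genes, 4 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.928). Abcc4, the reductase Akr1d1 (0.37) and the bile salt exporter Abcb11 (0.26) rose, and Slco1a1, which is also on the male-biased list, fell. Of 18 drug metabolism genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.649), with Gstm3 (0.43) higher and Cyp2c54 (-0.38), Cyp2c50 (-0.29) and Cyp3a13 (-0.28) lower. Gstm3 has 2 probe sets, of which the brighter was used, and its difference lay between 0.399 and 0.615 over the alternatives. The cytochrome genes have near-identical paralogs, which leaves their values uncertain.

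The acute phase list was lower by camera at the preset correlation (adjusted p = 0.000822), but did not pass with an estimated correlation (adjusted p = 0.471) or by fry (adjusted p = 0.180). Of 22 measured, Orm3 rose and Saa4 (-0.36) and Crp (-0.14) fell (1 and 7 adjusted over the list alone). The per-array mean of -0.20 had an exact permutation p of 0.198 (0.285 adjusted over 33 lists). Saa2 (-1.44), Saa1 (-1.26) and Lcn2 (-0.93), chosen after their values were seen, had the lowest values of the list and did not pass, with control SDs of 1.31, 1.28 and 0.898. The Crp call was lost in 8 of the 10 fits without 1 array, up to 0.0894 without control 5.

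Among markers of other cell types, 4 of 9 cholangiocyte genes rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00197; adjusted p = 0.248 with an estimated correlation). They were the keratins Krt18 (0.50) and Krt8 (0.48), which hepatocytes also express, Sox9 (0.33) and Cldn7 (0.21). The last was lost in 7 of the fits without 1 array, up to an adjusted p of 0.0931 without control 2. The bile duct markers Krt19 (0.09), Krt7 (0.12) and Epcam (0.07), chosen after their values were seen, did not pass when adjusted over all genes. Krt7 was the further gene that rose when adjusted over the list alone, while Krt19 and Epcam did not pass there either. The per-array mean was 0.21 higher (exact permutation p = 0.00794, 0.0327 adjusted over 33 lists). The Kupffer cell list had 1 called gene of 18, Cd9 (0.31; 1 and 0 adjusted over the list alone; camera adjusted p = 0.128), and the lymphocyte list 1 of 16, Cd8b1 (0.16; 1 and 1 adjusted over the list alone; camera adjusted p = 0.792). In the stellate cell list it was Col1a2 alone of 17 genes (0.18; 0 and 0 adjusted over the list alone; camera adjusted p = 0.610). The adipose or pancreas list passed fry (adjusted p = 0.0240), and its per-array mean was 0.10 higher (exact permutation p = 0.0238, 0.0655 adjusted over 33 lists). It had Cel alone of 9 genes (0.21; 1 and 0 adjusted over the list alone; camera adjusted p = 0.128). All of these calls were lost in some fits without 1 array: up to 0.0638 for Cd9 without HDAC3-depleted 4, 0.0852 for Cd8b1 and 0.0858 for Cel without control 2, and 0.0974 for Col1a2 without control 3. Limma called 0 of 10 neutrophil and 0 of 14 sinusoidal endothelial genes (0 in either direction adjusted over the list alone; camera adjusted p = 0.928 and 0.916), where the smallest adjusted p values were those of Ngp (-0.14) and Tek (-0.11). These were the only genes of either list with an unadjusted p under 0.05, and fry gave adjusted p values of 0.698 and 0.599. Of 4 measured red blood cell genes, too few for camera, Alas2, the erythroid enzyme of heme synthesis, fell by 0.86 (SE 0.08, adjusted p = 2.45e-05) and the other 3 did not pass (2 and 1 adjusted over the list alone). The hemoglobin genes were not analysed here.

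Stress, growth and identity lists did not pass camera. Of 17 p53 and DNA damage genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.177), with Btg2 (0.48), Eda2r (0.47), Aen (0.33) and Phlda3 (0.26) higher. Of 16 immediate early genes, Btg2 and Jun (0.40) rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.177), and the per-array mean was 0.14 higher (exact permutation p = 0.00794, 0.0327 adjusted over 33 lists). Of 24 cell cycle genes, Pcna rose (0.16) and Ccne2 fell (-0.48), or 1 and 1 adjusted over the list alone (camera adjusted p = 0.177). Herpud1 alone of 19 unfolded protein genes fell (-0.25; 0 and 1 adjusted over the list alone; camera adjusted p = 0.111). Of 18 interferon genes, Oasl1 rose (0.20) and Irf7 fell (-0.33), or 1 and 1 adjusted over the list alone (camera adjusted p = 0.294). Of 17 hepatocyte genes, Cebpa alone rose (0.30; 1 and 0 adjusted over the list alone; camera adjusted p = 0.792), and of 9 fetal liver genes Ly6d alone (0.35; 1 and 0 adjusted over the list alone; camera adjusted p = 0.916). Calls of Jun, Pcna, Ccne2, Herpud1, Oasl1, Irf7, Cebpa and Ly6d were lost in between 1 and 7 of the fits without 1 array, up to adjusted p values of 0.0551 (Jun), 0.0684 (Ccne2), 0.0556 (Herpud1), 0.0983 (Oasl1) and 0.0673 (Cebpa) without control 2, 0.0663 (Pcna) and 0.0639 (Ly6d) without control 3, and 0.0512 (Irf7) without control 4.

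Across the 32 lists tested, 7 passed camera at the preset correlation, 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05, and 12 passed fry. The uptake, glycolysis, respiration, female-biased, adipose or pancreas, p53 and immediate early lists passed fry but not camera. All of them were higher, with fry adjusted p values between 0.000795 and 0.0240. The male-biased and acute phase lists passed camera but not fry. The median, the mean and the camera direction differed in sign for the NCoR, other histone deacetylase, circadian clock, bile acid, lipoprotein, drug metabolism, hepatocyte, fetal liver and neutrophil lists, none of which passed camera. Gpat4, Fasn, Pdk4, Per2, Cebpa, Ly6d, Cd9, Cd8b1, Col1a2, Cldn7, Cel, Ccne2, Crp, Oasl1 and Jun also lost their call under another normalization, with array weights, with another variance model or in a fit on all probe sets. For Hdac3, Serpina7, Hdac4, Clock, Dbp, Bhlhe40, Agpat2, Akr1d1, Apom, Gbe1, Pygl, Cyp17a1, Cd8b1 and Krt8, 1 array of 1 group stood apart from the other arrays of that group.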

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

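The comparison with other splits of the arrays was planned, and its threshold was set before the result was seen. Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, gave 1228 or more genes in 1 direction. This makes chance assignment of the arrays unlikely for the higher genes, though 1 of 100 is the smallest share this comparison could give. The same held for the 1110 lower genes, again with 1 of 100 splits, and the highest count in another split was 2 in either case. For changes of at least 1.5-fold, the 66 higher and the 43 lower genes were each reached in 1 of 100 splits, with 1 gene as the highest count elsewhere. The count of gene lists behaved otherwise: 26 of 100 splits gave 7 or more lists past camera at the preset correlation, and another split gave 12. Chance assignment is therefore not excluded for the number of lists called.

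Single arrays stood far from the rest of their group for some named genes, by the gap to the nearest array over the range of the group. Among 220 combinations of gene and group, 14 lay past Dixon's limit, where chance gives about 11. In HDAC3-depleted 3, Hdac3 (0.735), Hdac4 (0.747) and Dbp (0.823) were lowest and Serpina7 (0.869) was highest. In HDAC3-depleted 4, Clock (0.783) and Akr1d1 (0.806) were lowest and Krt8 (0.760) highest, and in HDAC3-depleted 5, Gbe1 (0.791) and Pygl (0.768) were lowest. Cd8b1 was highest in HDAC3-depleted 1 (0.711). Among controls, Bhlhe40 was highest in control 5 (0.772), Cyp17a1 highest in control 1 (0.892), Agpat2 lowest in control 4 (0.772) and Apom lowest in control 2 (0.736). Hdac3 in HDAC3-depleted 3 read 9.31 against 9.54 for the next array, so the array apart had the least Hdac3 signal.

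Probe sets outside the gene tests also differed between the groups. Of 12146 probe sets with no listed gene symbol, 446 passed limma's adjusted p of 0.05 in a fit on all probe sets, 148 higher and 298 lower. That is a smaller share than the 11.7% of genes called in the gene fit, which was adjusted over the tested genes alone. Changes of at least 1.5-fold were a larger share: 148 of these 12146 probe sets, against 66 higher and 43 lower of 19938 genes in the gene fit. What these probe sets measure was not examined. The largest differences were 1.14 for probe set 10605338, 1.11 for 10497481, -1.38 for 10343835 and -1.29 for 10587776. Of 1621 probe sets with several symbols, 141 passed, 40 higher and 101 lower.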

How the results depend on the processing

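Cyclic loess normalization was the only alternative chosen after the data were seen. All 2338 called genes kept their sign in every alternative that tested them, and the Hdac3 difference stayed between -1.39 and -1.30 and past the threshold. The counts moved more. At an adjusted p under 0.01, 429 genes were higher and 412 lower, by construction. Leaving out 1 array gave 792 to 1743 higher and 729 to 1288 lower genes, with 817 and 729 without control 2, 792 higher without control 3, and 1743 and 1288 without control 1; the cause was not tested. Counts of at least 1.5-fold changes ranged from 60 to 75 higher and 41 to 52 lower in those fits. Gene lists past camera numbered 7, and these 7 passed in each of the 19 other settings run at the preset correlation. Array weights gave 11 lists and leaving out 1 array 7 to 13, with 13 without HDAC3-depleted 3, where cholesterol synthesis, Kupffer cell and 4 further lists were added. An estimated correlation gave 0 lists, and fry, which asks another question, 12. Quantile normalization called 2531 genes, 59.6% of them higher, and cyclic loess 2377, 2095 shared with the 2338. The numbers in the titles do not pair the mice: correlations of deviations between arrays of equal number were -0.21, -0.06, 0.08, -0.11 and 0.10, and 1 of 5 control arrays correlated best with its own number. With the replicate number as a block, 825 genes were higher and 770 lower (1595 in all, 1542 shared), the Hdac3 difference was -1.36 and 7 lists passed. Of 92 called named genes, 67 kept an adjusted p under 0.05 in every alternative fit that tested them. The other 25 were lost when 1 array was left out, 11 of them also with the block. The stricter threshold of 0.01 was not part of this count, and some of the 67 miss it, such as Idi1 (limma adjusted p = 0.0169). Signal over background was not measured, so which dim genes lie at the floor is unknown; leaving out genes under the 30th percentile called 2608.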

Other observations

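The tests of time of day, of Rev-erb targets, of adipose tissue and of gene families by symbol were chosen after the results they bear on were seen, and those of time of day and of adipose tissue were also run in other forms before the ones given here, some with other verdicts. The 2 tests of genes named Zfp against an intensity offset and against single arrays were set before their results were seen.

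Other genes with small p values and no place on the lists, named after their values were seen, describe more of the change. Csrp3, a muscle LIM protein, rose 1.88-fold (log2 difference 0.91, SE 0.05, limma adjusted p = 6.97e-07), and the sialyltransferase St6gal1 rose by 0.68 on the log2 scale. The phosphatase Phospho1 (1.85-fold), the mitochondrial dicarboxylate carrier Slc25a10 (1.61-fold) and the ectonucleotidase Nt5e (2.06-fold) rose as well. Among genes that fell were Ociad2 (1.67-fold lower) and Rprd1a (1.54-fold lower). The transcript 9030619P08Rik, which has no gene name, rose 4.68-fold (log2 difference 2.23, SE 0.13, adjusted p = 8.76e-07), more than any named gene.

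Of the 10 tested genes nearest Hdac3 on its chromosome, 0 passed limma's threshold, and their adjusted p values lay between 0.235 and 0.898.

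Arntl, Clock and Nfil3 were higher in the depleted livers. A different time of day of collection was set against the other 15 measured clock genes, of which 4 (Nr1d1, Per1, Ciart and Bhlhe41) had a 95% interval that reached the size of the lower bound of 0.426 for Arntl, while those of Dbp, Tef, Per3 and Usp2 did not, so a difference in hour stays open. A candidate explanation is loss of repression through Rev-erb proteins, which recruit HDAC3 to Arntl, Clock, Nfil3 and Cry1. Of these 4 genes 3 rose, but those 3 are the pattern itself and cannot test the explanation. Cry1 alone could, and it fell (-0.24), which goes against the explanation for Cry1. Its call was lost in 4 of the 10 fits that left out 1 array. Loss of repression stays open for the other 3 genes. So does the GFP virus in the control group, which the design does not separate from the loss of HDAC3.

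The per-array means of fatty acid oxidation and fatty acid synthesis genes were both higher, by 0.193 (exact permutation p = 0.00794, 0.0327 adjusted over 33 lists) and by 0.266 (exact permutation p = 0.0159, 0.0524 adjusted, which misses the threshold). In camera the lists had an adjusted p = 0.359 and an adjusted p = 0.471 with an estimated correlation. Carried-over adipose tissue would raise its abundant transcripts at least as much. The mean of Adipoq, Fabp4, Plin1 and Plin4, chosen after the data were seen, differed by 0.04 (upper 95% bound 0.140, below both shifts). Fabp4 differed by -0.08, Plin4 by -0.08, Adipoq by 0.13 and Plin1 by 0.20 (upper bound 0.369). The adipose or pancreas list fixed in advance was 0.10 higher (exact permutation p = 0.0238, 0.0655 adjusted over 33 lists) and passed fry (adjusted p = 0.0240). The mean of the 4 genes stayed below both shifts, but it cannot decide the question. The genes were chosen after the data were seen, and the upper 95% bounds of Plin1 (0.369) and Adipoq (0.274) lay above 0.193. Carried-over adipose tissue, as the whole or a part of the cause, stays open. A difference in feeding stays open: a test of whether both means differed in the same direction was run and dropped, because it restates the pattern. Loss of HDAC3 and batches of handling also stay open and were not tested as causes.

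Genes whose symbol is Zfp and a number, which encode zinc finger proteins, were lower more often than other genes: of 347 measured, 46 were lower and 11 higher, where 19.3 lower were expected (Fisher's exact p = 4.39e-08 across genes, which are not independent; adjusted p = 9.49e-06 over 324 symbol families, and 0.0248 among genes above the 30th percentile of mean level). The comparison with all genes includes 1027 Olfr genes, of which 2 were lower, and 167 Vmn genes, of which 0 were. An intensity offset between arrays does not remove it: 54 were lower after cyclic loess normalization, 44 after quantile normalization and 40 after median centring. No single array carries it, since leaving out 1 array gave between 30 (without control 2 or control 4) and 69 (without control 1) lower genes, each above the number expected (largest Fisher's exact p = 8.96e-05). Probes shared between these paralogs remain open, because no probe sequences were used here, and so does the loss of HDAC3, which was not tested as a cause.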
